A study of Mus musculus with 12 samples.

How the data were processed

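RNA sequencing of mouse small intestine was taken as deposited, in 12 libraries of 4 groups with 3 libraries each. Per the labels' protocols, total RNA was extracted with the QIAamp AllPrep kit and libraries were made with the TruSeq RNA kit, with the strand setting not stated. Per the submitters' processing notes, the authors aligned reads with STAR and made the FPKM values with Cufflinks and Cuffnorm, whose versions are not given, and the notes name the builds mm10 and GRCm38. The scaling that Cuffnorm applied between libraries, the annotation release and the read length are not stated. The single deposited table holds 1 FPKM value per gene and library for 55484 genes, and all 12 of its columns were matched to a labelled sample (0 columns not mapped). The FPKM values are neither counts nor transcript fractions, so the depth per library and the precision it sets are unknown, and the spread between the 3 libraries of a group is the only measure of precision used.

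Of the gene identifiers in the table, 55224 (99.5%) occur in GENCODE M21, which gave the GRCm38 coordinates in the text. The gene names are those of the deposited table. List members whose symbol it lacks were matched through RefSeq symbols and synonyms. Symbols carried by several entries numbered 114, and each entry was tested as its own gene. 29436 genes were above 0 in no library. Genes at 1 FPKM or more in at least 3 libraries were kept, which left 12847. The log2 of FPKM + 1 was fitted with limma 3.58.1 in R 4.3.3, with all 12 libraries in 1 fit, 1 mean per group and 8 residual degrees of freedom, so that the groups share the estimate of the spread. The moderated t test used an intensity trend. P-values were adjusted by the Benjamini-Hochberg method within each of 6 comparisons, and genes were called at an adjusted p under 0.05. The 4 main comparisons were Melphalan against Control, each combined group against Melphalan, and the combined groups against each other. The 2 others set the combined groups against Control. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

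Gene lists, 48 in number, were written before the data were examined, as were the groups, the comparisons, the tests, the filter, the alternatives and the rule for naming genes. The 44 lists with at least 5 tested members went into limma's camera test with its preset correlation of 0.01 between members, adjusted over the lists of a comparison. The test was repeated with the correlation of the members estimated from the residuals. As the p53 list shows in the results, that form differs from the preset one in more than the correlation. Members were also counted after adjusting the limma p-values over the list alone. Some genes sit on more than 1 list: the p53 list shares Bax, Sesn2 and Btg2 with others, and the Paneth list shares Ang4, Pla2g2a and Clps with others.

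The rule for naming genes took, in each main comparison, the 6 highest and 6 lowest fold changes among called genes whose libraries do not overlap between the groups and whose higher mean is 5 FPKM or more. It left out predicted genes, variable segments, small RNAs and sex-linked genes. It added the 3 members with the smallest p of at most 8 lists called by camera, and a fixed set of 10 marker genes as values. For the comparisons of the combined groups with Control it took the 3 highest and the 3 lowest. Where fewer than 3 genes were called, the 5 with the smallest p were named as not called. Genes outside the rule were chosen after their values were seen. Among them are the clock genes, marked so in the text, and Hbb-bs, Ighm, Cr2, Cxcr5 and mt-Nd4.

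For the return of the melphalan genes, both comparisons use the Melphalan libraries, which alone produces a negative covariance between them. That part was computed from the residual variance of the fit and taken off the covariance and off the variance of the drug change before their ratio was formed. It was also simulated in 100 draws with no change in any group. Each draw gave a library's deviations from its group mean a random sign, the same for all its genes. Where the libraries of a group draw the same sign these deviations cancel, which leaves that group mean without noise. Scripts were tested on simulated data in the same design, with changes added to 50 genes at each size: of those, 4%, 38%, 96% and 96% were recovered at true log2 changes of 0.5, 1, 2 and 3. Of 121 genes called there, 4 (3.31%) were false. The list test called the list that was moved and 0 of 40 that were not. Shares returned of 0, 0.5 and 1 were estimated at 0.0126, 0.488 and 0.998. The simulated genes were drawn independently, with the same spread in every group. These tests thus do not cover lists with correlated members, or groups of unequal spread. In the data the mean residual variance ran from 0.0806 in MSC+Mel to 0.42 in Melphalan.

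The alternatives were a pseudocount of 0.1, no filter, a mean of 5 FPKM or more, quantile normalization, median-of-ratios rescaling, a fit on the 6 libraries compared, array weights, no intensity trend, the replicate number as a block, an added bound of 1 on the log2 fold change, the estimated correlation for lists, and leaving out each library in turn. Added after the data were seen were a split of the Melphalan libraries into 1 and 2, a fit without Melphalan 2 and Mel+MSC 3 and a fit without genes listed at 0 in a library beside 20 FPKM or more in another of its group. Whether the replicate numbers pair libraries was read from the correlation of their deviations from the group means, since the labels do not say. Between Control and Melphalan all 3 same-numbered pairs correlated above 0.1 (0.124, 0.233 and 0.184, beside -0.184 to 0.0412 for the 6 other pairs), so the fit with the block is given beside the results it changes there. With 3 against 3 libraries the smallest p an exact test can give is 0.1, so the moderated test of limma was used. Reads, splice forms and sequences of the human cells were not analysed here. Some results for single genes that the rule or the lists hold are not reported here.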

Results

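Gene expression in the mouse small intestine was measured by RNA sequencing in 12 libraries, 3 in each of 4 groups. The groups are Control, Melphalan, Mel+MSC and MSC+Mel. Melphalan is an alkylating chemotherapy drug that crosslinks DNA and injures tissues that renew quickly, such as the intestinal lining. MSC stands for mesenchymal stem cells, here from human umbilical cord. The series asks how such cells bear on melphalan injury of the intestine. The labels give no dose, no time and no meaning for the order of the names, so Mel+MSC and MSC+Mel are used only as the names of 2 groups. They give no hour of collection either. The labels do not say whether the libraries come from separate animals, so every p-value measures only the spread between these libraries, which may be technical.

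The deposited values are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) for 55484 genes, of which 12847 passed the filter and were tested. Read depth is unknown, because the values are not counts. The FPKM of a library summed to between 516851 and 796980, and between 11529 and 12703 genes reached 1 FPKM. Spearman correlations between libraries of a group were 0.943 to 0.957 in Control, 0.829 to 0.933 in Melphalan, 0.907 to 0.957 in Mel+MSC and 0.972 to 0.981 in MSC+Mel. The mean residual variance of a gene on the log2 scale ran from 0.0806 in MSC+Mel to 0.42 in Melphalan. Melphalan 2 and Mel+MSC 3 lay at the ends of the first principal component, at 70.2 and -54. The second component held nearly as much variance (25.8% beside 26.2%). On it Melphalan 1 lay at -57.3 and Mel+MSC 1 at -45, opposite Melphalan 2 at 38.1. Control 3 had the lowest mean of the G2 and M phase genes among the Control libraries, 2.85 on the log2 scale beside 3.84 and 3.95. Values are given as mean ± SD of 3 libraries, and fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Genes listed at exactly 0 in a library are given library by library, because such a 0 also occurs in mitochondrial genes that every cell uses.

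Melphalan against Control asked what the drug changed. The p53 target list was higher in the Melphalan libraries (adjusted p = 0.0104 with an estimated correlation). Cell cycle, crypt stem cell and Paneth cell lists were lower by limma's camera test with its preset correlation alone (adjusted p = 0.423, 0.517 and 0.517 with an estimated correlation), and few of their members passed singly. Olfm4, a marker of the stem cells at the crypt base (ENSMUSG00000022026, chromosome 14, 79984081 to 80023139, plus strand), fell from 280 ± 170 FPKM in Control to 5.84 ± 3 in Melphalan (log2 fold change -5.18, SE 0.59, adjusted p = 0.00744). Ccnb2, the mitotic cyclin B2 (chromosome 9, 70407692 to 70421547, minus strand), fell from 24.8 ± 8.3 to 5.33 ± 1.3 FPKM (-1.99, SE 0.25, adjusted p = 0.00903). Phlda3, a p53 target that restrains AKT signalling (chromosome 1, 135766119 to 135769136, plus strand), rose from 2.27 ± 0.91 to 15.9 ± 4.4 FPKM (2.37, SE 0.29, adjusted p = 0.00786).

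The 29 tested genes of the G2 and M phase list all had a fitted change below 0, with a median of -1.26. Over all genes 6 of them fell, and adjusted over the list alone 29 did. Nusap1, a spindle protein, fell from 13.3 ± 4.4 to 2.9 ± 1.1 FPKM (adjusted p = 0.0176), and Ccna2, cyclin A2, fell from 27.9 ± 9.7 to 7.94 ± 2.7 (adjusted p = 0.0207). Mki67, the proliferation marker, stood at 5.04 ± 3.7 beside 15.5 ± 5.9 FPKM and missed the threshold (adjusted p = 0.0786). The list stood apart from other genes in limma's camera test (adjusted p = 9.96e-23), but not once the correlation of its members was estimated from the data (adjusted p = 0.423 with an estimated correlation). Of 28 S phase genes, 1 fell over all genes and 1 adjusted over the list alone, Prim1, a DNA primase subunit, from 8.74 ± 2.2 to 3.24 ± 1.6 FPKM (adjusted p = 0.0459, and 0.0627 with the replicate number as a block). The S phase median was -0.59 (camera adjusted p = 1.44e-06, and adjusted p = 0.517 with an estimated correlation).

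Among 19 crypt stem cell genes Olfm4 fell over all genes and 8 genes fell adjusted over the list alone (median -0.52, camera adjusted p = 1.06e-05, and adjusted p = 0.517 with an estimated correlation). Prom1 stood at 18.7 ± 10 beside 56.6 ± 18 FPKM (adjusted p = 0.0696), and Lgr5 lay below the filter at 0.308 ± 0.4 beside 0.783 ± 0.063 FPKM. Among 19 genes of Paneth cells, the antimicrobial cells of the crypt base, 2 fell over all genes and 9 adjusted over the list alone. Defa26, an alpha-defensin of a family so alike that its values are uncertain (chromosome 8, 21618183 to 21618972, plus strand), fell from 44 ± 17 to 3.26 ± 1.2 FPKM (-3.38, adjusted p = 0.00786). Ang4, an antimicrobial ribonuclease, fell from 41.2 ± 19 to 9.15 ± 2 FPKM (adjusted p = 0.0292). Lyz1, the Paneth cell lysozyme, stood at 127 ± 23 beside 320 ± 100 FPKM and missed the threshold (adjusted p = 0.115). The Paneth median was -1.53 (camera adjusted p = 1.63e-08, and adjusted p = 0.517 with an estimated correlation). Clca3b fell from 75 ± 40 to 7.7 ± 3.3 FPKM (adjusted p = 0.0136). Gsdmc4, of the gasdermin C cluster on chromosome 15 whose members are near-identical and thus uncertain, was listed at 36.3, 29.2 and 13.4 FPKM in Control and at 0, 0.048 and 0.406 in Melphalan (adjusted p = 0.00237). Gsdmc2 was listed at 14.2, 13.1 and 7.59 FPKM and at 0, 0.209 and 0.129 (adjusted p = 0.00358).

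Of 31 p53 target genes, 8 rose over all genes, and adjusted over the list alone 14 rose and 1 fell. Ephx1, microsomal epoxide hydrolase (chromosome 1, 180976210 to 181020904, minus strand), rose from 2.95 ± 1.2 to 40 ± 21 FPKM (3.31, SE 0.42, adjusted p = 0.00903). Gdf15, a stress-induced cytokine, was listed at 0.0564, 0.439 and 0.2 FPKM in Control and 4.38, 2.68 and 4.06 in Melphalan (adjusted p = 0.0115). Cdkn1a, the cell cycle inhibitor p21, stood at 218 ± 77 beside 85.7 ± 23 FPKM and missed the threshold (1.29, adjusted p = 0.0573). Its limma adjusted p was 0.0151 without Melphalan 2, 0.0359 without Control 3, 0.029 after quantile normalization and 0.0394 after median-of-ratios rescaling. Each of these fits called more genes than the main limma fit, with 409, 420, 187 and 201 beside 171. Its values in fits that called fewer, such as those without Control 1 or 2, are not given here. Mdm2, which degrades p53, stood at 25.3 ± 1 beside 17.7 ± 2.9 FPKM (adjusted p = 0.139). The p53 list was called by camera (median 0.50, adjusted p = 2.45e-08) and held its call with the estimated correlation (adjusted p = 0.0104 with an estimated correlation). It was the only list of 44 to do so. The estimated correlation between members was 0.00651 in this list and 0.639 in the G2 and M phase list. In the p53 list it lay below the preset 0.01, yet the camera adjusted p rose from 2.45e-08 to 0.0104. The 2 forms of the test thus differ in more than the correlation. A call lost with the estimated correlation is not read as the effect of correlation alone.

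Enterocyte genes lay higher as groups. Of 24 genes of lipid absorption, Scarb1, a lipoprotein receptor, rose over all genes, from 0.972 ± 0.19 to 4.69 ± 1.4 FPKM (adjusted p = 0.0285), and 7 rose adjusted over the list alone (median 0.79, camera adjusted p = 3.66e-07, and adjusted p = 0.517 with an estimated correlation). Of 22 genes of brush border digestion 0 rose over all genes by limma and 7 adjusted over the list alone (median 0.68, camera adjusted p = 3.66e-07, and adjusted p = 0.517 with an estimated correlation). Alpi, intestinal alkaline phosphatase, stood at 358 ± 160 beside 152 ± 31 FPKM (adjusted p = 0.0901), and Sis, sucrase-isomaltase, at 2030 ± 930 beside 1630 ± 380 (adjusted p = 0.78). Of 30 genes of xenobiotic metabolism, Gsta3, a glutathione transferase with close paralogs, rose from 4.37 ± 1.6 to 26.5 ± 9.1 FPKM (adjusted p = 0.0176), and 6 rose adjusted over the list alone (camera adjusted p = 9.76e-05, and adjusted p = 0.679 with an estimated correlation). Outside these lists Aqp3, an aquaporin that carries water and glycerol, rose from 4.57 ± 0.66 to 34.5 ± 14 FPKM (adjusted p = 0.00786). Slc13a2, a citrate transporter, rose from 22.6 ± 11 to 114 ± 40 (adjusted p = 0.022), and Acta1, skeletal muscle actin, from 1.02 ± 0.12 to 12.5 ± 7.3 (adjusted p = 0.0224, and 0.0595 for each of the 2 with the replicate number as a block). The macrophage list (median 0.65, camera adjusted p = 0.000664, and adjusted p = 0.517 with an estimated correlation) stood at 1.14 without Melphalan 1 and lost its call without Melphalan 2 (0.38, adjusted p = 0.0885), the library with a B cell list mean of 6.28 beside 2.88 to 4.03 in Control.

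limma called 171 genes, 64 higher and 107 lower, and 2336 had an unadjusted p under 0.05. The count was 9 without Control 1, 18 without Control 2 and 420 without Control 3. It was 123 without Melphalan 1, 409 without Melphalan 2 (52.6% of them higher, beside 37.4%) and 38 without Melphalan 3. A fit on these 6 libraries alone called 4. With the replicate number as a block limma called 73. Of the 19 called genes named by the rule, 7 kept their call whichever of the 6 libraries compared was left out: Olfm4, Gsdmc4, Gsdmc2, Defa26, Ephx1, Aqp3 and Phlda3. In the limma fit on these 6 libraries alone Olfm4, Ephx1, Aqp3 and Phlda3 lost it (adjusted p = 0.0963, 0.0748, 0.0724 and 0.0748). Gsdmc4, Gsdmc2 and Defa26 kept it there.

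**Figure D1:**
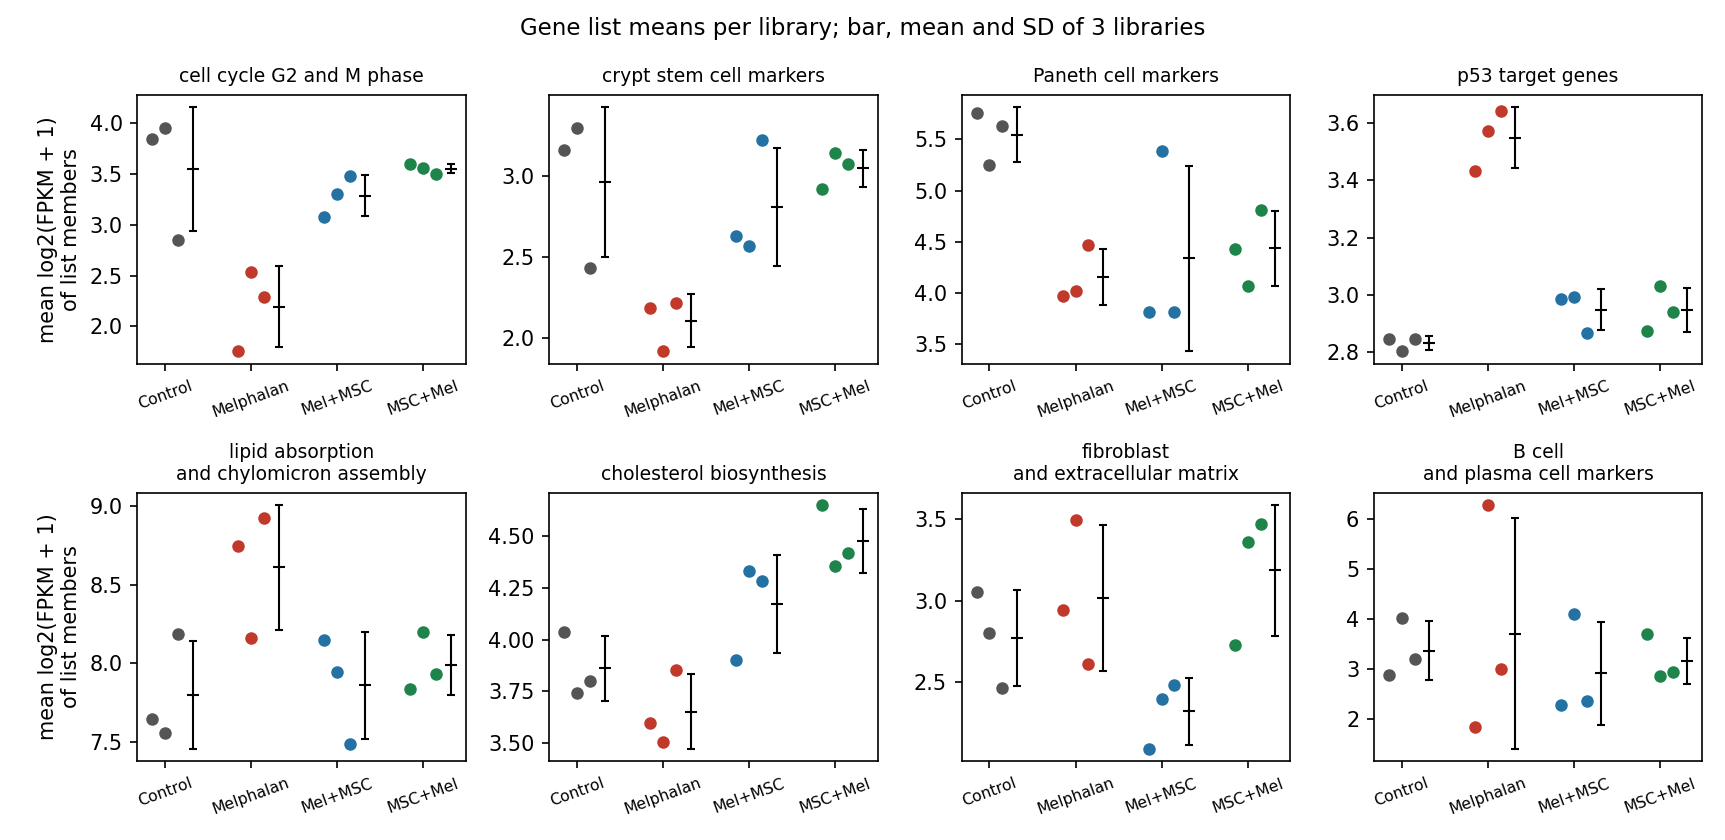
Mean log2(FPKM + 1) of the members of 8 gene lists in each library (points, 3 per group) with the mean and SD of each group (bars) on the y axis and the 4 groups on the x axis. The p53 list lies at 2.83 ± 0.025 in Control, 3.55 ± 0.11 in Melphalan, 2.95 ± 0.071 in Mel+MSC and 2.95 ± 0.077 in MSC+Mel, and Melphalan 2 stands apart in the B cell list at 6.28.

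Mel+MSC against Melphalan asked how the intestine of the first combined group differed from that of the drug alone. The p53 target list was lower in Mel+MSC (adjusted p = 0.0093 with an estimated correlation). The stem cell and the G2 and M phase lists were higher by limma's camera test with its preset correlation alone (adjusted p = 0.432 and 0.268 with an estimated correlation). Olfm4 rose from 5.84 ± 3 to 153 ± 73 FPKM (4.50, SE 0.59, adjusted p = 0.0232) and Ccnb2 from 5.33 ± 1.3 to 18.4 ± 2.6 (1.63, SE 0.25, adjusted p = 0.0378). Phlda3 fell from 15.9 ± 4.4 to 3.82 ± 1.5 FPKM (-1.82, SE 0.29, adjusted p = 0.0381), and Plk2, a stress-induced kinase and p53 target, from 6.37 ± 1.9 to 1.22 ± 0.55 (-1.73, SE 0.25, adjusted p = 0.0284). Myb, a transcription factor of crypt progenitors, rose from 2.52 ± 0.18 to 10.8 ± 3.1 FPKM (adjusted p = 0.0381), and Slc1a1, a glutamate transporter, from 3.32 ± 0.8 to 17.1 ± 4 (adjusted p = 0.0204).

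All 29 G2 and M phase genes had a fitted change above 0 (median 1.05). Ccnb2 rose over all genes and 23 genes rose adjusted over the list alone, and camera called the list (adjusted p = 3.36e-20, and adjusted p = 0.268 with an estimated correlation). Ccna2 stood at 24.3 ± 1.9 beside 7.94 ± 2.7 FPKM (adjusted p = 0.0792) and Mki67 at 12 ± 2.2 beside 5.04 ± 3.7 (adjusted p = 0.215). Among stem cell genes Olfm4 rose over all genes and 3 rose adjusted over the list alone (median 0.46, camera adjusted p = 3.15e-05, and adjusted p = 0.432 with an estimated correlation), and without Mel+MSC 3 the list median was 0.28 (0.275). Of 31 p53 target genes 3 fell over all genes, namely Phlda3, Plk2 and Gdf15, and 15 fell adjusted over the list alone (median -0.48, camera adjusted p = 2.01e-08, and adjusted p = 0.0093 with an estimated correlation). Gdf15 was listed at 0.54, 0.502 and 0 FPKM in Mel+MSC beside 4.38, 2.68 and 4.06 in Melphalan (adjusted p = 0.0284). Cdkn1a stood at 116 ± 19 beside 218 ± 77 FPKM (adjusted p = 0.26) and Mdm2 at 15.2 ± 0.68 beside 25.3 ± 1 (adjusted p = 0.128).

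Paneth cell genes were not called as a list. Their median change was 0.10 (camera adjusted p = 0.372), with 0 members called by limma over all genes and 0 adjusted over the list alone. Lyz1 stood at 159 ± 88 beside 127 ± 23 FPKM (adjusted p = 0.864). Of 24 genes of the cholesterol synthesis list 6 rose adjusted over the list alone (median 0.44, camera adjusted p = 1.37e-07, and adjusted p = 0.277 with an estimated correlation). Lipid absorption genes had a median of -0.46 (-0.70 (-0.697) without Melphalan 2), with 0 of 24 fitted above 0 and 0 called by limma, over all genes or adjusted over the list alone (camera adjusted p = 1.37e-07, and adjusted p = 0.359 with an estimated correlation). Apoa4, an apolipoprotein of chylomicrons, stood at 1840 ± 1200 beside 5380 ± 2200 FPKM (adjusted p = 0.221).

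Fibroblast, endothelial and macrophage lists were lower in Mel+MSC than in Melphalan by limma's camera test with its preset correlation alone. The T and B cell lists were not lower once Melphalan 2 was left out, as given below. The fibroblast list had a median of -0.65 (-0.34 (-0.344) without Melphalan 2), with 0 genes called by limma over all genes and 2 lower adjusted over the list alone (camera adjusted p = 1.26e-07, and adjusted p = 0.373 with an estimated correlation). The endothelial list had a median of -0.68 with 8 lower adjusted over the list alone, and the macrophage list a median of -0.99 (-1.62 without Melphalan 1) with 0 (camera adjusted p = 1.37e-07 for each, and adjusted p = 0.269 with an estimated correlation for each). The regenerative epithelium and YAP target list had a median of -0.82 with 3 lower adjusted over the list alone (camera adjusted p = 4.36e-07, and adjusted p = 0.111 with an estimated correlation). Single genes outside these lists fell, among them Sema7a, a membrane-bound semaphorin, from 11.3 ± 1.9 to 2.22 ± 0.76 FPKM (adjusted p = 0.0284), and Ly6c1, a surface protein of endothelial and myeloid cells, from 14.1 ± 2.5 to 4.51 ± 0.34 (adjusted p = 0.0232). Without Melphalan 2 the T cell list, at -0.72 in the fit of all libraries, stood at 0.00 (0.00137), and the B cell list, at -0.87, stood at 0.59. Without Melphalan 1 they stood at -1.20 and -1.86, and the B cell list at -1.40 without Melphalan 3 and at -0.50 (-0.497), -1.51 and -0.55 (-0.548) without Mel+MSC 1, 2 and 3.

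limma called 20 genes, 14 higher and 6 lower, beside 1747 with an unadjusted p under 0.05. The count fell to 4 without Melphalan 1, 0 without Melphalan 3, 2 without Mel+MSC 1, 0 without Mel+MSC 2 and 2 without Mel+MSC 3, and 0 of the 12 called genes named by the rule held in every such fit. With the replicate number as a block limma called 3. Olfm4, Ccnb2, Phlda3, Plk2, Gdf15, Myb and Slc1a1 then lost their call, while Gsdmc4, Sema7a and Ly6c1 kept it.

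MSC+Mel against Melphalan asked the same of the second combined group. The p53 target list was lower in MSC+Mel (adjusted p = 0.0282 with an estimated correlation). The stem cell, G2 and M phase and cholesterol synthesis lists were higher by limma's camera test with its preset correlation alone (adjusted p = 0.674, 0.524 and 0.524 with an estimated correlation). Olfm4 rose to 241 ± 38 from 5.84 ± 3 FPKM (5.26, SE 0.59, adjusted p = 0.00737), and Ccnb2 to 21.7 ± 1 from 5.33 ± 1.3 (1.86, SE 0.25, adjusted p = 0.0103). Muc2, the main secreted mucin of goblet cells (chromosome 7, 141690340 to 141754693, plus strand), rose to 6.17 ± 2.7 from 0.312 ± 0.12 FPKM (2.39, SE 0.43, adjusted p = 0.0327). The goblet cell list as a whole was not called (median 0.18, camera adjusted p = 0.177). The call of Muc2 was lost without Melphalan 1 or 3 (adjusted p = 0.0863 and 0.0787) and without MSC+Mel 1, 2 or 3 (0.102, 0.141 and 0.141). Phlda3 fell to 3.05 ± 0.75 from 15.9 ± 4.4 FPKM (-2.04, SE 0.29, adjusted p = 0.0128).

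Of 29 G2 and M phase genes 7 rose over all genes and 27 adjusted over the list alone, with all 29 fitted above 0 (median 1.37). Mki67 rose to 18.2 ± 0.65 from 5.04 ± 3.7 FPKM (adjusted p = 0.0466), Nusap1 to 11.3 ± 0.2 from 2.9 ± 1.1 (adjusted p = 0.0289) and Ccna2 to 25.9 ± 2.8 from 7.94 ± 2.7 (adjusted p = 0.031). Camera called the list (adjusted p = 1.96e-20, and adjusted p = 0.524 with an estimated correlation). Of 28 S phase genes 1 rose over all genes and 3 adjusted over the list alone (median 0.76, 0.51 (0.505) without Melphalan 1, camera adjusted p = 2.27e-06, and adjusted p = 0.675 with an estimated correlation). Prim1 was the S phase gene called, at 9.35 ± 0.92 beside 3.24 ± 1.6 FPKM (adjusted p = 0.0377). Of 19 stem cell genes 2 rose over all genes and 10 adjusted over the list alone (median 0.74, camera adjusted p = 2.27e-06, and adjusted p = 0.674 with an estimated correlation). Beside Olfm4 this was Ephb2, a receptor that positions cells along the crypt, at 7.45 ± 1.4 beside 1.41 ± 0.3 FPKM (adjusted p = 0.028). Of 31 p53 target genes Phlda3, Plk2 and Gdf15 fell over all genes and 13 fell adjusted over the list alone (median -0.51, camera adjusted p = 2.27e-06, and adjusted p = 0.0282 with an estimated correlation). Cdkn1a stood at 106 ± 11 beside 218 ± 77 FPKM (adjusted p = 0.105, and 0.0351 without Melphalan 2). The limma fit without Melphalan 2 called 401 genes, the most of the fits without 1 library in this comparison.

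Of 24 genes of the cholesterol synthesis list 15 rose adjusted over the list alone (median 0.80, camera adjusted p = 2.49e-10, and adjusted p = 0.524 with an estimated correlation). Idi1, an isomerase of the pathway, rose to 43.9 ± 7.9 from 7.82 ± 3.4 FPKM (adjusted p = 0.0345), Fdft1, squalene synthase, to 16.4 ± 3.9 from 5.8 ± 1.2 (adjusted p = 0.0244) and Lss, lanosterol synthase, to 5.1 ± 0.75 from 1.13 ± 0.5 (adjusted p = 0.0338). Of 16 heat shock genes 1 fell over all genes and 8 adjusted over the list alone (median -0.63, camera adjusted p = 0.000192, and adjusted p = 0.638 with an estimated correlation). It was Hspa1b, an inducible chaperone with a near-identical neighbour and thus uncertain, at 1.23 ± 0.32 beside 13.2 ± 6.3 FPKM (adjusted p = 0.0313). Paneth cell genes had a median of 0.37, with 0 called by limma over all genes and 1 higher adjusted over the list alone (camera adjusted p = 0.177). The brush border list, with a median of -0.34 (camera adjusted p = 0.0343, and adjusted p = 0.804 with an estimated correlation), stood at 0.10 after quantile normalization and lost its call without Melphalan 1, Melphalan 3 (median -0.14 (-0.137)) or MSC+Mel 3 (adjusted p = 0.0553, 0.437 and 0.0656).

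Outside the lists Clca3b rose to 108 ± 6.6 from 7.7 ± 3.3 FPKM, and Fgfbp1, a carrier of fibroblast growth factors, to 15.7 ± 0.99 from 0.613 ± 0.33 (adjusted p = 0.00737 for each). Tspan1, a tetraspanin, rose to 29.5 ± 4.2 from 3.21 ± 2 FPKM (adjusted p = 0.0338). Gsdmc4 was listed at 15.9, 7.49 and 9.98 FPKM in MSC+Mel beside 0, 0.048 and 0.406 in Melphalan (adjusted p = 0.00737). G6pc, glucose-6-phosphatase, fell to 19.2 ± 2.1 from 65.7 ± 20 FPKM (adjusted p = 0.0418), and Ier5, an immediate early gene, to 10.3 ± 0.58 from 35.2 ± 9.6 (adjusted p = 0.0289). Rpph1, the RNA of RNase P, was listed at 0.961, 0.972 and 0.472 FPKM in MSC+Mel beside 20.9, 18 and 13.9 in Melphalan (adjusted p = 0.0345). Erdr1 was listed at 0.26, 0.26 and 0 beside 5.75, 9.81 and 7.58 (adjusted p = 0.0337).

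limma called 159 genes, 105 higher and 54 lower, beside 2852 with an unadjusted p under 0.05. The count was 18 without Melphalan 1, 401 without Melphalan 2, 32 without Melphalan 3, and 8, 6 and 16 without MSC+Mel 1, 2 and 3 in turn, and 5 of the 24 called genes named by the rule held in every such fit, among them Olfm4, Clca3b, Fgfbp1 and Gsdmc4. The others lost their call in at least 1, among them Mki67, Nusap1, Ccna2, Idi1, Fdft1, Lss and Ephb2. With the replicate number as a block limma called 20. Nusap1, Ccna2, Prim1, Idi1, Fdft1, Lss, Tspan1, Erdr1, Hspa1b, Ier5 and G6pc were among those that then lost their call. Olfm4, Clca3b, Fgfbp1, Gsdmc4, Ccnb2, Phlda3 and Rpph1 were among those that kept it. Of the called genes 66% were higher in the fit of all libraries, 59.4% without Melphalan 2 and from 84.4% to 100% without each of the other 5 libraries compared. Without both Melphalan 2 and Mel+MSC 3 limma called 2114, of which 46.2% were higher.

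**Figure D2:**
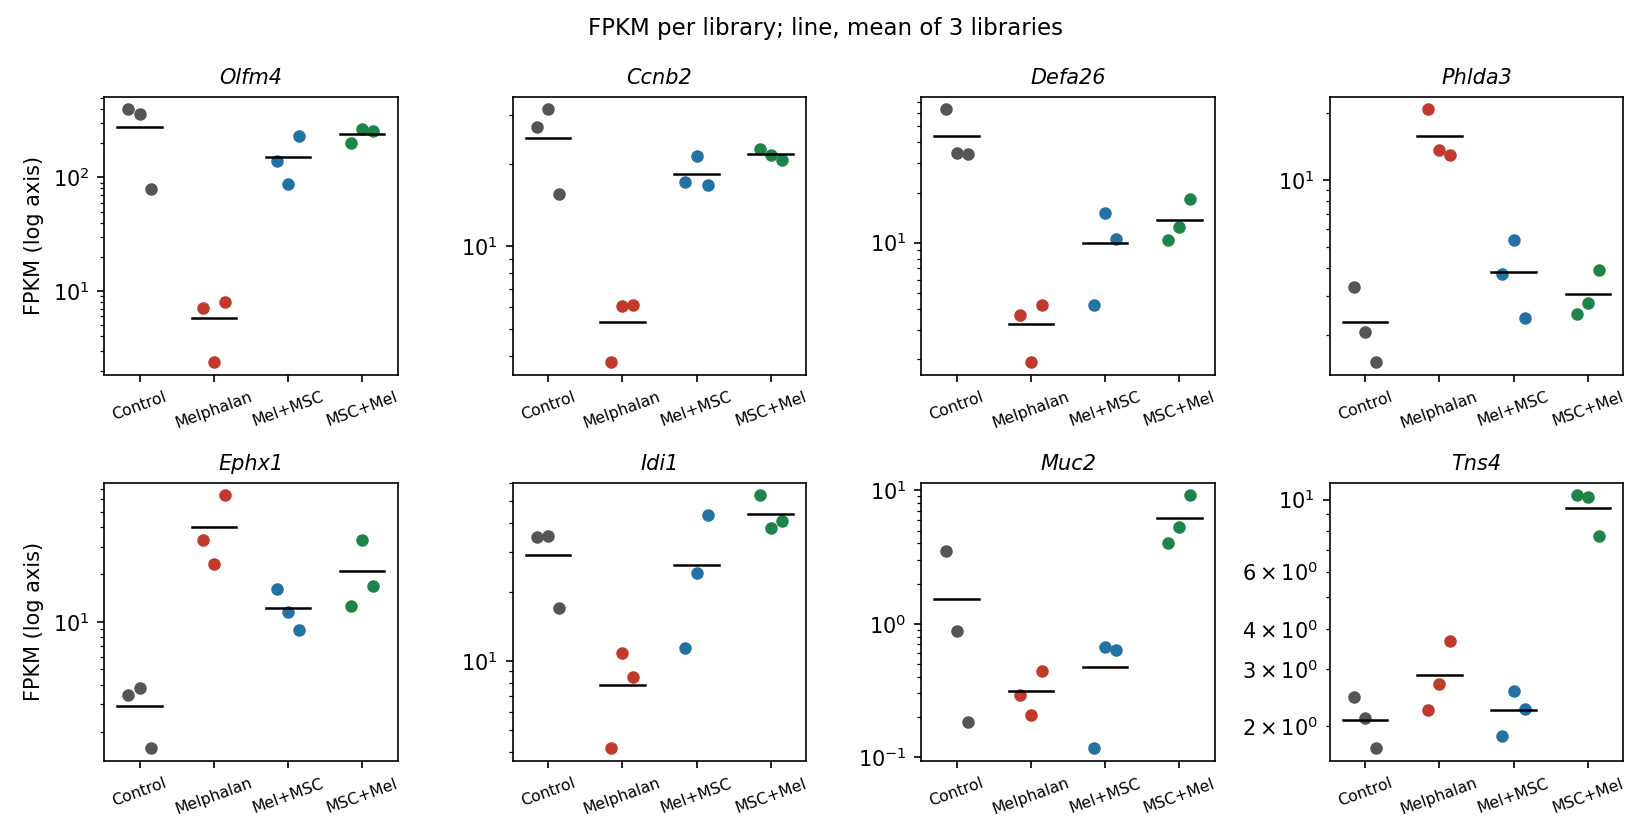
FPKM of 8 genes in each library (points, 3 per group; line, mean) on a log y axis, with the 4 groups on the x axis. Olfm4 averages 5.84 FPKM in Melphalan beside 280 in Control, 153 in Mel+MSC and 241 in MSC+Mel, and Tns4 averages 9.39 in MSC+Mel beside 2.24 in Mel+MSC.

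The return of melphalan genes, such as Olfm4, Ccnb2 and Phlda3, was then counted over the 171 genes called between Melphalan and Control. In Mel+MSC 168 of them (98.2%) moved toward Control relative to Melphalan and in MSC+Mel 163 (95.3%) did. Such a move also arises by chance because both comparisons use the same Melphalan libraries: in 100 simulated draws that held the drug change and no effect of the cells, 70.1% and 73.6% of called genes moved so on average, and at most 91.3% and 92.1%. Genes called in the opposite direction against Melphalan numbered 16 in Mel+MSC and 55 in MSC+Mel. Independent lists would share 0.146 and 1.14. Simulated groups with no change shared up to 482 and 202 (median 0), and with the drug change alone up to 1992 and 365 (median 0). Each draw turned whole libraries, so a group mean could keep no noise or carry a single library's pattern across all genes. The ends of these ranges reflect that, so that both counts lay inside them decides nothing. The median gene had returned by 70.5% in Mel+MSC and 65.1% in MSC+Mel, and 36 and 57 of the 171 had returned by less than 50%. Choosing genes by their drug change builds part of this in: with the drug change alone the simulated median was 19% on average (-27.9% to 54.6%) and 18.7% (-8.82% to 46.1%). These draws take the measured drug change as true, so they understate the part built in. Against Control 7 of the 171 were still called in MSC+Mel, and no such count can be read for Mel+MSC, where limma called 0 genes of any kind (694 at an unadjusted p under 0.05).

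Across 12847 genes, which are not independent replicates, the correlation of the drug change with the change against Melphalan was -0.704 for Mel+MSC and -0.673 for MSC+Mel. Simulated groups with no change gave -0.472 on average (from -1 to 0.369) and -0.538 (from -1 to 0.146). The covariance was -0.193 and -0.214 beside simulated values of -0.127 (-0.315 to 0.0443) and -0.125 (-0.278 to 0.00797), a difference of -0.0662 and -0.0893 from their means. Both lay inside the ranges, which decides nothing. A correlation of -1 arises in draws where the means of Control and the combined group coincide, and the ranges come from the same draws. In a check chosen after the data were seen, 1 Melphalan library entered the drug change and the other 2 the return, or the reverse, so that the comparisons shared none. The covariance then ran from -0.14 to 0.0198 for Mel+MSC, below 0 in 4 of 6 splits, and from -0.159 to 0.00919 for MSC+Mel, below 0 in 5 of 6. Because these splits did not all fall below 0, a return across all genes was not separated from the sharing of the Melphalan libraries.

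Corrected for the shared libraries, the share of the drug change returned was estimated at 54.7% in Mel+MSC and 76.3% in MSC+Mel. Over the splits it ran from -20.5% to 145% and from -9.51% to 164%. With all Melphalan libraries in both comparisons it ranged from 2.15% without Mel+MSC 3 to 159% without Melphalan 3 in the first, and was 85.9% without Melphalan 1. In the second it ranged from 66.5% without Melphalan 1 to 125% without Melphalan 3.

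MSC+Mel against Mel+MSC compared the combined groups with each other. Fibroblast, endothelial and macrophage lists were higher in MSC+Mel, and smooth muscle, ribosomal protein and heat shock lists were lower, by limma's camera test with its preset correlation alone: 0 lists were called with an estimated correlation (adjusted p from 0.62 to 0.819 for these). Tns4, tensin 4, which links integrins to the cytoskeleton (chromosome 11, 99065678 to 99089306, minus strand), was the 1 gene called, higher at 9.39 ± 1.5 beside 2.24 ± 0.36 FPKM (1.68, SE 0.2, adjusted p = 0.0378). All 24 fibroblast genes had a fitted change above 0 (median 0.83), with 0 called by limma over all genes and 9 higher adjusted over the list alone (camera adjusted p = 2.54e-12, and adjusted p = 0.62 with an estimated correlation). Col6a1, a collagen VI chain, stood at 10.7 ± 4.9 beside 3.26 ± 0.75 FPKM (adjusted p = 0.222), and Col6a2 at 9.15 ± 4.3 beside 2.76 ± 0.65 (adjusted p = 0.215).

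Of 17 endothelial genes 16 were fitted above 0 and 5 were higher adjusted over the list alone (median 0.76, camera adjusted p = 7.46e-08, and adjusted p = 0.62 with an estimated correlation). Eng, endoglin, stood at 3.95 ± 0.9 beside 1.11 ± 0.46 FPKM (adjusted p = 0.234). The macrophage list had a median of 0.71 with 0 called adjusted over the list alone (camera adjusted p = 0.000466, and adjusted p = 0.819 with an estimated correlation). Ly6c1 stood at 11.9 ± 2.6 beside 4.51 ± 0.34 FPKM (1.21, adjusted p = 0.17). Of 20 smooth muscle genes 1 was fitted above 0, and adjusted over the list alone 1 was higher and 3 lower (median -0.50, -0.30 (-0.298) without Mel+MSC 1, camera adjusted p = 0.000224, and adjusted p = 0.819 with an estimated correlation). Des, desmin, stood at 24.1 ± 3.3 beside 46.4 ± 14 FPKM (adjusted p = 0.242), and Hhip, a hedgehog-binding protein, at 2.9 ± 1.1 beside 0.956 ± 0.25 (adjusted p = 0.274). Heat shock genes had a median of -0.47 with 1 lower adjusted over the list alone (camera adjusted p = 0.000406, and adjusted p = 0.819 with an estimated correlation). The ribosomal protein list (median -0.50, camera adjusted p = 2.13e-06, and adjusted p = 0.819 with an estimated correlation) had 0 called adjusted over the list alone and stood at -0.10 after quantile normalization (adjusted p = 0.45) and at -0.31 without Mel+MSC 1 or 2 (-0.312 and -0.309). The p53 list did not differ detectably, with a median of 0.00 (0.000155) and a camera adjusted p of 0.917. Olfm4 stood at 241 ± 38 beside 153 ± 73 FPKM (adjusted p = 0.631) and Cdkn1a at 106 ± 11 beside 116 ± 19 (adjusted p = 0.9). Muc2 stood at 6.17 ± 2.7 beside 0.472 ± 0.31 FPKM (2.24, adjusted p = 0.17, and 0.0408 without Mel+MSC 3). The limma fit without Mel+MSC 3 called 398 genes in this comparison, beside 1 in the main fit.

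Beside the 1 call of limma, 1562 genes had an unadjusted p under 0.05. Tns4 lost its call without Mel+MSC 1 or 2 (adjusted p = 0.331 and 0.164) and without MSC+Mel 1, 2 or 3 (0.101, 0.46 and 0.11), and 398 genes were called without Mel+MSC 3, 16.3% of them higher in MSC+Mel. Without both Melphalan 2 and Mel+MSC 3 limma called 1117, 27.3% of them higher.

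Mel+MSC against Control asked how far the first combined group lay from Control. Paneth and tuft cell lists lay below Control by camera with its preset correlation alone (adjusted p = 0.395 for each with an estimated correlation), and limma called 0 single genes, with 694 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0873. All 19 Paneth genes had a fitted change below 0 (median -1.35, and -0.84 (-0.838) without Mel+MSC 1), and 8 were lower adjusted over the list alone (camera adjusted p = 2.79e-14, and adjusted p = 0.395 with an estimated correlation). The Paneth mean of Mel+MSC 2, 5.38 on the log2 scale, lay within the Control range of 5.25 to 5.76, and those of Mel+MSC 1 and 3 were each 3.81. Of 12 tuft cell genes, a chemosensory cell type, 6 were lower adjusted over the list alone (median -0.62, camera adjusted p = 7.15e-07, and adjusted p = 0.395 with an estimated correlation), though in Melphalan the tuft mean was 2.17 ± 0.55 beside 2.01 ± 0.15 in Control and 1.34 ± 0.43 in Mel+MSC. The G2 and M phase list had a median of -0.26 (camera adjusted p = 0.00202, and adjusted p = 0.712 with an estimated correlation), a call lost without Control 1, Control 2 or Mel+MSC 1 (medians -0.14, -0.07 (-0.0719) and -0.11 (-0.112), adjusted p = 0.235, 0.703 and 0.147), and stood at -0.62 (-0.616) without Control 3. The p53 list had a median of 0.05 (camera adjusted p = 0.15).

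Ido1, which breaks down tryptophan, stood at 2.11 ± 1.3 beside 15.8 ± 4.4 FPKM (-2.50, adjusted p = 0.0873). Hba-a1, an alpha-globin with a near-identical copy and thus uncertain, was listed at 0.634, 0.621 and 0 FPKM in Mel+MSC beside 37.3, 11.7 and 13.9 in Control (adjusted p = 0.0873). The long noncoding 4930479H17Rik was listed at 0 in all 3 Mel+MSC libraries beside 5.35, 3.24 and 1.57 FPKM in Control (adjusted p = 0.0873), and at 0 in all 3 Melphalan libraries. limma called 1 gene without Control 3 and 1 without Mel+MSC 3.

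MSC+Mel against Control asked the same of the other group. Paneth, smooth muscle and heat shock lists were below Control and the cholesterol list was above it by limma's camera test with its preset correlation alone, and 0 lists were called with an estimated correlation (adjusted p from 0.572 to 0.658 for these). Aqp3 was higher at 33.1 ± 8.2 beside 4.57 ± 0.66 FPKM (2.59, SE 0.32, adjusted p = 0.0194), near its level in Melphalan, as was Acta1 at 15.5 ± 5.5 beside 1.02 ± 0.12 (2.98, adjusted p = 0.0358). Acox2, a peroxisomal oxidase of bile acid synthesis, was higher at 6.56 ± 1.9 beside 0.628 ± 0.23 FPKM (adjusted p = 0.0374). Nfil3, a circadian repressor, was lower at 3.29 ± 1.5 beside 23 ± 9.9 FPKM (adjusted p = 0.0374), and Ypel2 at 3.25 ± 1.3 beside 13.7 ± 2.4 (adjusted p = 0.0194).

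All 19 Paneth genes had a fitted change below 0 (median -1.17), with 4 lower adjusted over the list alone (camera adjusted p = 2.97e-08, and adjusted p = 0.658 with an estimated correlation). All 20 smooth muscle genes did too (median -0.60), with 8 lower adjusted over the list alone (camera adjusted p = 2.97e-08, and adjusted p = 0.658 with an estimated correlation). Of 16 heat shock genes 7 were lower adjusted over the list alone (median -0.71, camera adjusted p = 3.29e-09, and adjusted p = 0.572 with an estimated correlation). Of 24 cholesterol genes 12 were higher and 1 lower adjusted over the list alone (median 0.65, camera adjusted p = 2.39e-10, and adjusted p = 0.572 with an estimated correlation). The G2 and M phase list had a median of 0.00 (-0.000898) and a camera adjusted p of 0.938, and the p53 list a median of 0.08 and a camera adjusted p of 0.268. Olfm4 stood at 241 ± 38 beside 280 ± 170 FPKM (adjusted p = 0.978).

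limma called 22 genes, 8 higher and 14 lower, beside 1508 with an unadjusted p under 0.05. The count was 8, 6 and 0 without Control 1, 2 and 3 and 0, 0 and 5 without MSC+Mel 1, 2 and 3, so that 0 of the 6 genes named by the rule held in every such fit.

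**Figure D3:**
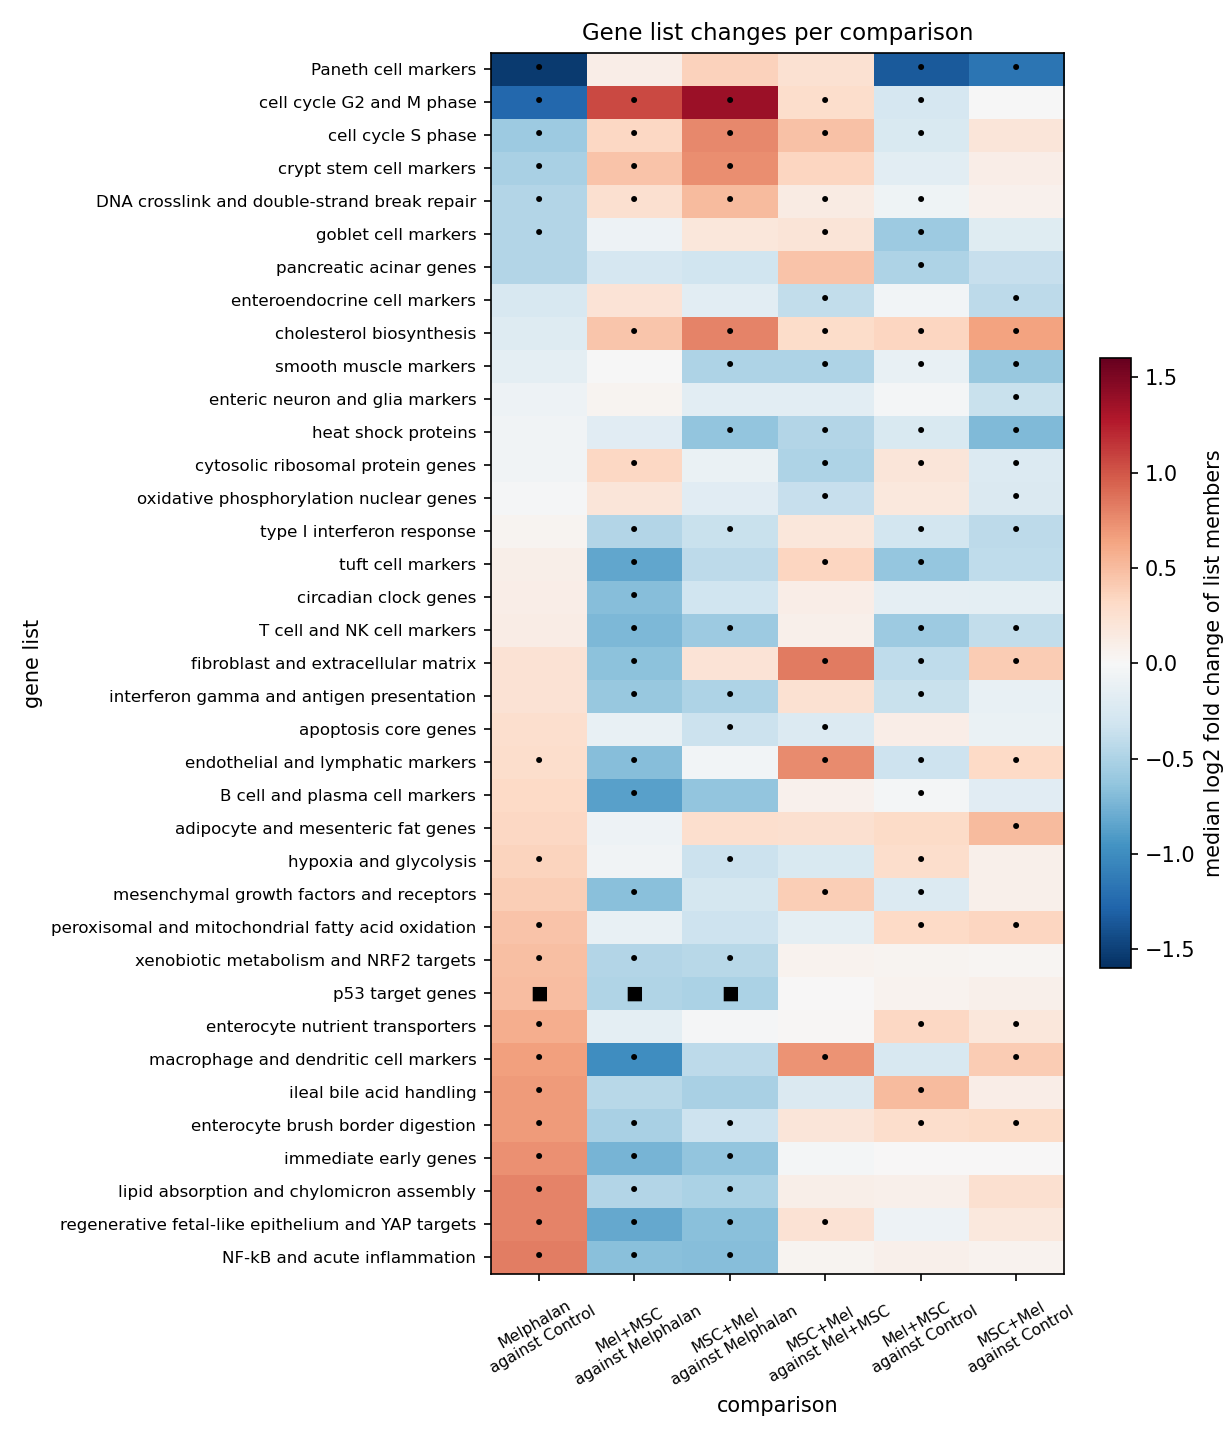
Median log2 fold change of the members (colour, from -1.6 to 1.6) of the 37 gene lists (y axis) that camera called in at least 1 of the 6 comparisons (x axis). Dots mark camera calls with the preset correlation alone and squares those that also held with an estimated correlation, which are the p53 list in the comparisons of Melphalan with Control, of Mel+MSC with Melphalan and of MSC+Mel with Melphalan.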

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

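The alternatives were set before the data were examined, except the fit without Melphalan 2 and Mel+MSC 3, the fit without genes listed at 0 beside 20 FPKM and the split of the Melphalan libraries, which were chosen after seeing the data. Values are given in the order Melphalan against Control, Mel+MSC against Melphalan, MSC+Mel against Melphalan, MSC+Mel against Mel+MSC, Mel+MSC against Control and MSC+Mel against Control, for which limma called 171, 20, 159, 1, 0 and 22 genes and camera 19, 23, 19, 17, 23 and 17 lists. Except where an alternative's own construction shows it the cause was not tested.

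With no filter, which tests more genes, the counts were 63, 1, 50, 2, 2 and 19. With a mean of 5 FPKM or more the second was 13 and the fourth 0, and camera called 8 lists in the fourth. Quantile normalization gave 13 in the second, 0 in the fourth and 52 in the last (48.1% of them higher, beside 36.4%), and median-of-ratios rescaling gave 42 in the last and 14 in the second (57.1% of them higher, beside 70%). A pseudocount of 0.1 gave 2 in the fourth and 1 in the fifth. The 6 libraries compared gave 4, 0, 636 (49.2% of them higher, beside 66%), 1, 0 and 55 (50.9%). That fit has fewer samples and takes the spread from the groups compared alone. Their mean residual variance was 0.176 in Control, 0.42 in Melphalan, 0.293 in Mel+MSC and 0.0806 in MSC+Mel. Array weights, whose estimate did not converge, gave 3543 (54.9% of them higher, beside 37.4%), 2282 (48.4%), 5417 (44.7%), 5051 (44.5%), 226 (58.4%) and 952 (51.3%). Without Melphalan 2 and Mel+MSC 3 the counts were 990 (53.5% of them higher), 2, 2114 (46.2%), 1117 (27.3%), 2 and 113 (47.8%). The estimated correlation left 1, 1, 1, 0, 0 and 0 lists. Dropping the trend or the genes listed at 0 beside 20 FPKM moved no count by over 1.5 times.

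The replicate number as a block gave 73, 3, 20, 0, 1 and 5 genes. Of 18 same-numbered pairs 7 correlated above 0.1 (from -0.369 to 0.396), and 5 of 12 libraries correlated best with their own number. Only between Control and Melphalan did all 3 pairs do so, and there the block changed the calls of Acta1, Slc13a2 and Prim1 and of no other gene named by the rule and no list. Elsewhere the labels leave a pairing open. Between Melphalan and Mel+MSC 2 of 3 same-numbered pairs correlated above 0.1 (from -0.177 to 0.396, beside -0.427 to 0.252 for the 6 other pairs). With the block camera called 19, 23, 19, 17, 22 and 17 lists.

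Leaving out 1 library gave from 9 to 420, 0 to 16, 6 to 401, 0 to 398, 0 to 1 and 0 to 8 genes, and from 19 to 24, 21 to 27, 14 to 21, 9 to 18, 16 to 26 and 11 to 19 lists. The share of the drug change returned, 54.7% in Mel+MSC and 76.3% in MSC+Mel, ran from 2.15% to 159% and from 66.5% to 125%. It was 40.8% and 78.6% with a pseudocount of 0.1 and 58.9% and 72.7% after quantile normalization. With separate Melphalan libraries in the drug change and the return it changed sign, from -20.5% to 145% in Mel+MSC and from -9.51% to 164% in MSC+Mel. A group left with 2 libraries was assumed to vary like the others.

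The direction of the list test reversed in the following, given as medians. In Mel+MSC against Melphalan the B cell list stood at 1.01 with array weights, 0.88 (0.881) without Melphalan 2 and Mel+MSC 3 and 0.59 (0.592) without Melphalan 2. There the T cell list stood at 0.05 (0.0537) and 0.00 (0.00137) in the latter 2 fits, and the NF-kB list at 0.14 (0.143) with array weights. In MSC+Mel against Melphalan the T cell list stood at 0.08 (0.0806) in both of those fits and the brush border list at 0.10 (0.0971) after quantile normalization. In MSC+Mel against Mel+MSC the goblet cell list stood at -0.32 (-0.322) with array weights and -0.10 (-0.0978) without Melphalan 2 and Mel+MSC 3. In Mel+MSC against Control the smooth muscle list stood at 0.00 (0.0042) without Control 1. Medians also crossed 0 where camera kept its direction and lost its call. The B cell list in Mel+MSC against Control (-0.03, -0.0321) stood at 0.42 (0.419) with array weights, 0.08 (0.0751) without Melphalan 2 and Mel+MSC 3 or Mel+MSC 3 alone, 0.26 (0.255) without Control 2 and 0.12 (0.121) without Mel+MSC 1. In the same comparison it kept its call at -1.01 without Mel+MSC 2, -0.59 (-0.587) without Control 1 and -0.37 (-0.374) without Control 3 (camera adjusted p = 0.00041, 0.00791 and 0.0477). There the DNA repair list stood at 0.01 (0.00981) after quantile normalization, and in MSC+Mel against Mel+MSC the goblet cell list at -0.10 (-0.0978) without Mel+MSC 3. Over the fits without 1 library the lowest values of these lists were -1.86 (B cell) and -1.20 (T cell) in Mel+MSC against Melphalan, -1.21 (T cell) in MSC+Mel against Melphalan and -0.31 (-0.307, smooth muscle) in Mel+MSC against Control.

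Of 1994 values of single genes under other settings 1717 kept their side of the threshold, 133 lost it, 144 gained it and 0 reversed, and in fits without 1 library 864 of 1110 kept it, 218 lost it, 28 gained it and 0 reversed. A gene counted as reversed only where its sign changed and at least 1 of the 2 fits called it. A sign change between uncalled values counted as kept. For lists only the 118 results called by camera in the main fit were followed. Of 1283 such values 1171 kept the call, 104 lost it and 8 reversed. Without 1 library 584 of 708 kept the call, 120 lost it and 4 reversed. Depth limits the low genes to an unknown degree, because the values are not counts.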

Other observations

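The levels of clock genes stood in opposite orders across the groups. They are described here after their values were seen, from a list fixed before. Arntl, the activator of the molecular clock, stood at 20.1 ± 2.3 FPKM in Control, 9.91 ± 1.9 in Melphalan, 13.4 ± 1.7 in Mel+MSC and 6.94 ± 3.2 in MSC+Mel, and Nfil3, which cycles with it, fell between Control and MSC+Mel (limma adjusted p = 0.0374). Nr1d2, which represses Arntl, stood at 4.42 ± 1.5, 12.5 ± 2.7, 7.85 ± 3.7 and 19.3 ± 4.4 FPKM, and Dbp, an output gene of the clock, at 0.685 ± 0.16, 7.69 ± 0.83, 2.09 ± 2 and 15 ± 11. For Arntl and Nr1d2 the limma adjusted p between MSC+Mel and Control was 0.0542 each. Because its members move in opposite directions, the list test of camera, which looks for 1 direction, gave an adjusted p of 0.778 in that comparison, though adjusted over the list alone 4 of 16 members were higher and 4 lower. In Mel+MSC against Melphalan camera called the list lower (median -0.68, adjusted p = 0.00628, and adjusted p = 0.359 with an estimated correlation), a call lost without Melphalan 1 (-0.45, adjusted p = 0.118). The labels give no hour of collection, so whether the groups were collected at the same hour is unknown for every comparison. MSC+Mel lay furthest from Control in Arntl, Nr1d2 and Dbp, while its G2 and M phase mean was 3.55 beside 3.54 in Control and 2.19 in Melphalan, its p53 mean 2.95 beside 2.83 and 3.55, and its Olfm4 mean 241 FPKM beside 280 and 5.84.

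Of the tests below, those on the cell cycle pattern and the test of melphalan on B cell genes were written after the result was seen, and the others before. The cell cycle tests first used a bound of 2 SE. They were rewritten with 95% intervals after a first run in which the return part lay just beyond that bound, and the rewriting left that test undecided.

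Cell cycle and crypt genes such as Ccnb2 and Olfm4 were lower in Melphalan and higher again in the combined groups. A smaller share of crypt tissue in the Melphalan samples would lower stem cell genes as far as G2 and M phase genes. The difference of the 2 list means was -0.50 (-0.497, SE 0.25, 95% interval -1.07 to 0.08 (0.079)), which leaves it open, and for the return in MSC+Mel the difference between G2 and M phase and Paneth genes was 1.07 (SE 0.54, -0.16 (-0.163) to 2.31), which leaves it open too. Without Melphalan 2 the G2 and M phase mean differed from Control by -1.52 (SE 0.34, -2.32 to -0.72 (-0.721)), which decides nothing, because that library had the highest mean of the 3 (2.53 (2.534) beside 1.76 (1.755) and 2.29) and leaving it out can only deepen the fall. The authors' scaling does not carry the fall of G2 and M phase genes in Melphalan, since after quantile normalization the mean differed by -1.38 (SE 0.29, -2.06 to -0.71 (-0.705)). This difference was not computed for crypt genes or for the return. After quantile normalization camera with its preset correlation kept its calls of the stem cell and G2 and M phase lists in Melphalan against Control. In Mel+MSC against Melphalan it kept both calls too.

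Hbb-bs, a beta-globin, was listed at 63.5, 11.1 and 13.7 FPKM in Control, 7.89, 1.62 and 0 in Melphalan, 0.297, 1.39 and 0 in Mel+MSC, and 0.0758, 0.304 and 0 in MSC+Mel. Hba-a1 was listed at 37.3, 11.7 and 13.9, then 4.26, 1.23 and 0, then 0.634, 0.621 and 0, then 0.241, 0 and 0, and the exact zeros are not read as absence. limma called Hba-a1 lower in Melphalan (adjusted p = 0.0239) and in MSC+Mel (adjusted p = 0.0194). Less blood in the treated tissue would lower platelet genes as well, but only 3 of them were detected, and their mean differed by -0.02 (-0.0172, SE 0.11) between the treated and the Control libraries. With most platelet genes below the filter the test decides neither way.

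B cell genes stood apart in Melphalan 2, where 20 of 25 members of the list had their highest value. Ighm, the IgM heavy chain, stood at 572 FPKM there and between 1.24 and 88.9 elsewhere. A lymphoid follicle in that sample predicts that follicle genes peak there: of 13 detected genes of follicles and their epithelium 11 were highest in Melphalan 2 (exact binomial p = 8.96e-11, against a chance of 8.33%, for genes that are not independent), as were 8 of the 10 on no other list. That chance takes each library as equally likely to be highest. Melphalan 2 had the most genes at 1 FPKM (12703) and the highest median of tested genes (9.02 FPKM), so the p is too small to an unknown degree. Cr2, of follicular dendritic cells, stood at 41.5 FPKM beside at most 4.02, and Cxcr5, the follicle homing receptor, at 31.5 beside at most 2.96. The drug as the cause was not borne out, since of the 3 Melphalan libraries 1 lay above every Control library in the B cell mean and 1 below.

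Other splits of the 6 libraries of a comparison into 3 and 3 number 10 with the real one, too few for a share under 0.05. As many genes as the real split were called in 1 of 10 splits for Melphalan against Control (171, highest other 5, and 1 among the 3 others that part all 3 same-numbered pairs as the real split does, while the remaining 6 part 1 pair), Mel+MSC against Melphalan (20, highest other 6), MSC+Mel against Melphalan (159, highest other 0), MSC+Mel against Mel+MSC (1, highest other 0) and MSC+Mel against Control (22, highest other 0). For Mel+MSC against Control all 10 did (0, highest other 470), and a split with 470 points to a structure of the samples, whose cause was not tested.

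Exact zeros occur in genes that every cell uses. Of 13 mitochondrial genes 4 were listed at 0 in all libraries, and mt-Nd4 was listed at 0 in Control 1, Control 3, Melphalan 1 and Mel+MSC 3 and between 4300 and 9440 FPKM elsewhere. In all, 127 genes were at 0 in a library beside 20 FPKM or more in another of its group, 116 of them in Melphalan 1.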
